A study of Citrus sinensis with 4 samples.

How the data were processed

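RNA was measured in 4 libraries of sweet orange fruit endocarp, 1 for each combination of 2 cultivars and 2 stages. Per the labels' protocols, endocarps were frozen, RNA was extracted with Trizol, mRNA was enriched by poly(A) selection and libraries were prepared by Illumina protocols. The aligner, the counting tool, the strandedness of the libraries, the genome build and the annotation are not given in the sources used here. Reads of a gene and of an overlapping gene on the other strand, and reads of near-identical gene copies, therefore cannot be separated with certainty.

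The deposited file of each library gives, per the file headers, a raw fragment count per gene, a scaled count and an FPKM value. The counts, raw per the file headers, are whole numbers, and they sum to between 14040916 and 16445383 per library. The deposited scaled count is a normalized signal, equal to the raw count times 1 factor per library for over 92% of the detected genes (within 1%). It was used only for this check. How the deposited FPKM values were computed is not given in the sources used here. They sum to between 2037507 and 4128618 per library, with very large values at some very short gene models. In the 50-day Bingtangcheng library a gene model of length 58 with 3 fragments was given an FPKM of 1033790. The FPKM values were therefore used only as an alternative. A header line recurring 1 time inside each file was skipped.

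The gene identifiers (22604 of the form Cs, 5832 of the form orange1.1t and 600 named Citrus_newGene) are not paired with names or descriptions in the files. Of these identifiers 0 matched the 29331 genes of the NCBI reference table for the Valencia assembly DVS_A1.0 supplied for naming. The 32 gene lists fixed before the data were examined, among them citrate metabolism, proton pumps, sugar transport, flavonoids and markers of seed, peel and vascular tissue, were defined on gene descriptions. They could not be filled, and no list was tested. No check for RNA of other tissues was possible for the same reason. Genes were grouped instead by chromosome, identifier form and mean level, and by on and off patterns, loss in a single library and neighbouring position. These groupings and their thresholds were chosen after the data were seen. So were the tests on them, except that of the Citrus_newGene models against lists matched on level, whose bounds were set before its result was seen. The fixed rule ranked the genes to name by the smaller of their 2 log2 ratios among those that met the size rule the same way in both pairs, and for the ratio of ratios by its size. It required a description, which none has, so that condition was dropped and the number named was reduced to 2 per direction and comparison. Genes named for their loss in a single library were chosen after their values were seen, as the 2 with the most fragments in the 50-day Bingtangcheng library.

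Counts were normalized with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 1.07 and 1.11 for the 50-day and 0.927 and 0.910 for the 70-day libraries of Dahongtiancheng and Bingtangcheng. Log2 ratios of normalized CPM (fragments scaled to a common effective library size) used a prior count of 2. A gene met the size rule where it had at least 10 fragments and 1 CPM in at least 1 of the 2 libraries, a ratio of at least 2-fold and a 99% exact conditional (Clopper-Pearson) counting interval that excluded 1. For the ratio of ratios, a fold of at least 2 was required as fixed before the data were examined. Its 99% interval, a normal one on the log scale from the 4 counts, each plus 0.5, replaced a first version that asked for any of the 4 pairs to meet the size rule. That change was made after the first count had been seen. Printed folds carry a 95% exact counting interval in parentheses. Against a count of 0 the fold is given as at least the value computed against 3 fragments in that library. That value leaves out the counting error of the other count, so the exact 95% interval starts lower. Counting intervals compare 2 libraries and say nothing of the spread between fruits or trees, because fragments without molecular identifiers are not independent molecules and each group has 1 library.

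As a secondary analysis, edgeR's quasi-likelihood test was fitted to all 4 libraries with cultivar and stage as additive terms. This leaves 1 residual degree of freedom per gene, and any true difference of the stage effect between cultivars counts as error. Its p-values measure the spread between these libraries only. The common dispersion was 0.0770. Benjamini-Hochberg adjustment was applied across 16692 genes.

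The scripts were tested on simulated data drawn for all 29036 genes from the real mean levels and totals, with 100 genes changed 3-fold and 100 changed 8-fold between the cultivars. The dispersion of 0.08 was chosen after the fitted value was known. It was the same for every gene, and no stage effect was simulated. With counting error only, the size rule at both stages recovered 89.0% of the 3-fold and 100% of the 8-fold changes and took up 0 unchanged genes. With a dispersion of 0.08 the edgeR fit recovered 53.0% and 94.0% of them, with 8 unchanged genes called.

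Alternatives fixed before the data were examined were median-of-ratios size factors, scaling by total counts, the deposited FPKM with a pseudocount of 1, no expression floor or 1 of 5 CPM, a prior count of 0.5, a fold threshold of 4, a counting interval of 95%, DESeq2 1.42.0, and edgeR without a filter or against a fold of 1.5. Added after the data were seen was the removal, in each pair, of the median log2 ratio of the tested genes of each of 20 bins of mean level. Expected overlaps are the product of the 2 list lengths over the genes expressed in both pairs, per direction. They give every gene the same chance of meeting the rule, whatever its level. The 2 cultivar ratios share no library, nor do the 2 stage ratios. Matched random lists were drawn 10000 times in 20 bins of mean level. Figures and tables were made with Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9.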

Results

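Poly(A) RNA of fruit endocarp, the inner layer of the fruit wall from which the juice sacs of citrus arise, was sequenced from 2 sweet orange cultivars, Dahongtiancheng and Bingtangcheng, at 50 and at 70 days after full bloom. Each of the 4 combinations of cultivar and stage was represented by 1 library, so no group had replicates and no p-value stands behind a difference between any 2 libraries. The tables listed 29036 genes and held 16253052 fragments for Dahongtiancheng and 14040916 for Bingtangcheng at 50 days, and 16192148 and 16445383 at 70 days. A single fragment corresponded to between 0.0576 and 0.0668 CPM (TMM-normalized fragments scaled to a common library size), and 3 fragments, the level that a count of 0 allows, to between 0.173 and 0.201. These limits, like every interval given here, cover counting error only. Between 15788 and 16485 genes per library had at least 10 fragments, while 7705 genes had none in any library. Genes are given by the identifiers and positions of the files, which pair them with no gene names. The genome build behind the positions is not given in the sources used here.

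The libraries lay closer by stage than by cultivar. Across genes, which are not independent replicates, the log2 levels of the cultivars correlated at r = 0.958 at 50 days and r = 0.923 at 70 days, whereas the stages correlated at r = 0.872 in Dahongtiancheng and r = 0.888 in Bingtangcheng. Across both cultivar and stage, r was 0.852 between Bingtangcheng at 50 days and Dahongtiancheng at 70 days, below both of these, and above both of these between Dahongtiancheng at 50 days and Bingtangcheng at 70 days. Expression was within 2-fold for 92.9% of the expressed genes between the cultivars at 50 days and for 86.0% at 70 days. Between the stages the share was 77.1% in Dahongtiancheng and 78.0% in Bingtangcheng. The most abundant genes took a larger part of the 70-day libraries. The 1000 most abundant genes of each library held 43.6% of its fragments (exact 95% binomial interval 43.5 to 43.6) in Dahongtiancheng and 42.0% (41.9 to 42.0) in Bingtangcheng at 50 days, against 49.6% (49.6 to 49.7) and 49.7% (49.7 to 49.8) at 70 days.

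The first comparison asked which genes differed between 50 and 70 days. A difference between stages cannot be told apart from anything else that the libraries of a stage shared, and the same holds for cultivars. A gene was counted as higher or lower where it reached the expression floor, differed at least 2-fold, and had a 99% counting interval of the ratio that excluded 1. In Dahongtiancheng 1551 genes were higher and 2046 lower at 70 days, out of 16211 expressed. In Bingtangcheng 1287 genes were higher and 2133 lower, out of 16199. Of these, 648 genes were higher in both cultivars and 1195 were lower in both, against 102 and 244 expected if the lists were independent. Only 130 genes went in opposite directions, fewer than the 317 expected, and log2 ratios in the 2 cultivars correlated at r = 0.623 across genes.

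The 648 genes higher at 70 days in both cultivars together held 4.58% of the fragments (exact 95% binomial interval 4.57 to 4.59) at 50 days and 14.7% (14.6 to 14.7) at 70 days in Dahongtiancheng, and 3.96% (3.95 to 3.97) and 11.4% (11.4 to 11.4) in Bingtangcheng. The 1195 lower genes held 1.14% (1.13 to 1.14) in Dahongtiancheng and 1.49% (1.48 to 1.49) in Bingtangcheng at 70 days, compared with between 5.99% and 6.01% and 6.93% (6.92 to 6.95) at 50 days. Among genes with a mean level over 50 CPM, 204 were higher and 110 lower in both cultivars. Among genes with a mean under 5 CPM, 193 were higher and 541 lower. The median log2 ratio of all expressed genes also rose with level, from -0.16 to 0.10 in Dahongtiancheng and from -0.36 to 0.21 in Bingtangcheng between the lowest and the highest of 3 equal groups. An alternative chosen after the data were seen removed the median of each of 20 bins of level. It left 119 genes higher and 161 lower over 50 CPM, and 260 and 396 under 5 CPM. That step takes out any shift that depends on level, so it cannot show whether the excess of higher genes at high levels is real. Over 50 CPM the excess was kept with median-of-ratios factors (209 higher and 109 lower) and the deposited FPKM (214 and 107). Scaling by total counts reversed it (119 and 186). Genes of both directions were spread over the genome, and the share of expressed genes that differed lay between 10.4% on chromosome 4 and 13.7% on chromosome 9. At least 4-fold differences in both cultivars were found for 191 higher and 488 lower genes.

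Among the genes higher at 70 days, Cs1g05770 (chromosome 1, 5556924 to 5558153, minus strand) stood first. It had 0 fragments in Dahongtiancheng and 1 in Bingtangcheng at 50 days, and 522 and 311 at 70 days. Its normalized level was at least 201-fold higher at 70 days in Dahongtiancheng, with a 95% counting interval that started at 163. In Bingtangcheng it was 324-fold higher (57.7 to 12831). Citrus_newGene_2305 (unplaced sequence, 44192043 to 44194611) followed, with 20 fragments at 50 days and 6768 at 70 days in Dahongtiancheng, a 392-fold difference (95% counting interval 253 to 642), and with 1 and 302 fragments in Bingtangcheng, a 314-fold difference (56.0 to 12461). Among the lower genes, Cs4g04780 (chromosome 4, 2850637 to 2852144, plus strand) dropped from 865 to 13 fragments in Dahongtiancheng and from 1111 to 11 in Bingtangcheng. These are 57.5-fold (33.4 to 108) and 97.0-fold (54.0 to 195) lower levels. Cs4g02820 (chromosome 4, 1377231 to 1379047, minus strand) had 101 and 171 fragments at 50 days and 0 in both libraries at 70 days, at least 29.1-fold and 54.7-fold lower. The 95% counting intervals of these folds started at 23.2 and 44.0.

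With cultivar as a second term, an additive fit used the libraries of both cultivars as replicates of a stage. The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 542 genes higher and 809 lower at 70 days at 5% among 16692 genes, and 1205 of these 1351 genes were among those that met the size rule in both cultivars. The 4 genes named above had adjusted p between 0.00962 and 0.0144 in this edgeR fit. The fit used the same libraries as the size rule, which had ranked these genes by ratios that agreed in both cultivars. The overlap and these p-values are therefore no independent support for the genes. The split between higher and lower genes depended on the scaling. With the libraries scaled to their totals alone, the median log2 ratio of all expressed genes moved by -0.20 in Dahongtiancheng and -0.28 in Bingtangcheng, and 449 genes were higher and 1617 lower in both cultivars. The split was then 1154 higher and 2607 lower in Dahongtiancheng, and 872 higher and 2997 lower in Bingtangcheng.

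**Figure D1:**
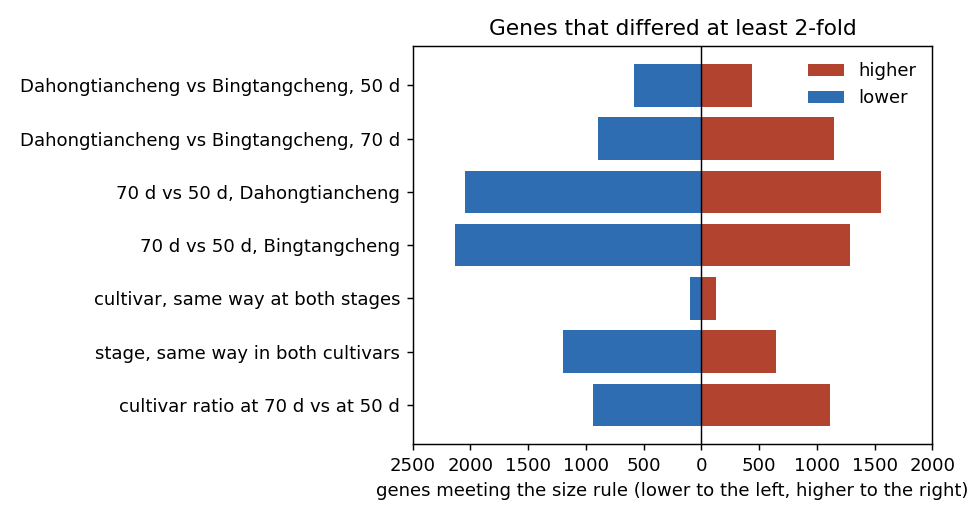
Number of genes that met the size rule in each comparison (horizontal axis, number of genes, lower to the left and higher to the right of 0; d, days after full bloom). Between the stages 1843 genes differed the same way in both cultivars, and between the cultivars 219 differed the same way at both stages.

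The next comparison asked how the cultivars differed at each stage. At 50 days 440 genes were higher and 585 lower in Dahongtiancheng than in Bingtangcheng, 6.35% of the 16139 expressed genes. At 70 days 1146 were higher and 896 lower, 12.8% of 15895. Few genes differed in the same way at both stages. There were 122 genes higher and 97 lower in Dahongtiancheng at both, against 22.1 and 22.4 expected from independent lists. The split depended on the rule, with 55 higher and 23 lower at a fold threshold of 4, and 140 and 80 with the deposited FPKM values. At 70 days alone, a threshold of 4 left 499 higher and 214 lower. At 50 days alone, 512 were higher and 476 lower with the medians of the level bins removed, so that the sign of the split changed. That step takes out any shift that depends on level, so it cannot by itself settle the sign. The alternatives fixed before the data were examined all kept more lower genes, from 414 higher and 660 lower with total counts to 156 and 160 with a fold threshold of 4. Another 154 genes differed in opposite directions at the 2 stages, against 44.8 expected. This expectation gives every gene the same chance of a call, and it was exceeded in both the same and opposite directions. The excess of genes that differed the same way is therefore by itself no evidence of lasting cultivar differences. Of the genes called at both stages, 58.7% kept their direction. Between the stages this share was 93.4% for the 2 cultivars. These shares are over genes called in both pairs. Over all genes expressed in both pairs, the cultivar ratios had the same sign at 50 and 70 days for 49.4% of 15342, and the stage ratios in both cultivars for 70.5% of 15718. Log2 ratios of the cultivars at 50 and at 70 days correlated at r = 0.127 across genes.

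The genes that differed between the cultivars at both stages were mostly weakly expressed. The mean level was under 5 CPM for 159 of the 219 genes, and over 50 CPM for 8. The 122 genes higher in Dahongtiancheng held 0.201% of its fragments (exact 95% binomial interval 0.198 to 0.203) at 50 days and 0.747% (0.743 to 0.752) at 70 days, against 0.0435% (0.0424 to 0.0446) and 0.147% (0.145 to 0.149) in Bingtangcheng. The group of genes with identifiers of the form Citrus_newGene, which are listed apart from the other gene models in the files, contributed 30 genes, 22 higher and 8 lower in Dahongtiancheng. That is 7.73% of the 388 expressed genes of this group, compared with 1.26% of all others. Random lists of other genes matched on mean expression held 14.5 such genes on average and at most 28 in 10000 draws. The share on the 9 numbered chromosomes ranged from 1.03% on chromosome 4 to 1.58% on chromosome 9, and it was 2.01% on unplaced sequence.

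Some of these genes had few or no fragments in 1 of the cultivars. Lower in Dahongtiancheng were orange1.1t02290 (unplaced sequence, 34428020 to 34428436), with 355 and 672 fragments in Bingtangcheng at 50 and 70 days and 0 in both Dahongtiancheng libraries, and Citrus_newGene_43 (chromosome 1, 20319063 to 20324426). The level of orange1.1t02290 was at least 132-fold lower in Dahongtiancheng at 50 days and at least 225-fold lower at 70 days. The 95% counting intervals of these folds started at 107 and 182. Citrus_newGene_43 had 4 fragments in Dahongtiancheng against 630 in Bingtangcheng at 50 days and 7 against 509 at 70 days, 176-fold (68.3 to 647) and 73.0-fold (35.2 to 182) lower. Citrus_newGene_2056 (unplaced sequence, 481516 to 485244) was higher in Dahongtiancheng, with 139 and 103 fragments against 0 in both Bingtangcheng libraries, at least 41.6-fold and 34.2-fold. The 95% counting intervals of these folds started at 33.3 and 27.3. The level of orange1.1t05568 (unplaced sequence, 88064361 to 88064636) was also higher, with 141 fragments against 0 at 50 days and 139 against 1 at 70 days. Its level was at least 42.2-fold higher at 50 days, with a 95% counting interval that started at 33.8, and 139-fold higher at 70 days (24.5 to 5511). By a rule chosen after the data were seen, 17 genes had at least 20 fragments in both Dahongtiancheng libraries and at most 2 in both Bingtangcheng libraries, and 10 genes showed the reverse. In crossed pairs of libraries 6 genes were on and off in this way.

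In the additive fit with stage as the second term, edgeR's quasi-likelihood test called 0 genes between the cultivars at an adjusted p of 0.05. The smallest adjusted p in this edgeR test was 0.0694. An unadjusted p under 0.05 was reached by 775 of 16692 genes. That is fewer than evenly spread p-values would give, so this number is by itself no evidence of cultivar differences. DESeq2 with the same terms called 47 genes higher and 18 lower. The 4 genes named above had adjusted p between 0.0694 and 0.239 in the edgeR fit. Data were also simulated with a dispersion of 0.08 between libraries, set near the fitted value. The size rule then recovered 96.0% of 8-fold and 67.0% of 3-fold cultivar differences at both stages. It also took up 91 unchanged genes at both stages and 1521 in the 50-day pair alone. The 1521 exceeded the 1025 genes called in the real 50-day pair, so the simulated spread was larger than that of this pair. They were fewer than the 2042 genes called in the real 70-day pair, so the same cannot be said of that pair. The simulated numbers therefore cannot be carried over to the 219 genes as a count of unchanged genes. They leave open that a part of the 219 reflects spread between libraries, and do not show which of the 1025 are cultivar differences.

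**Figure D2:**
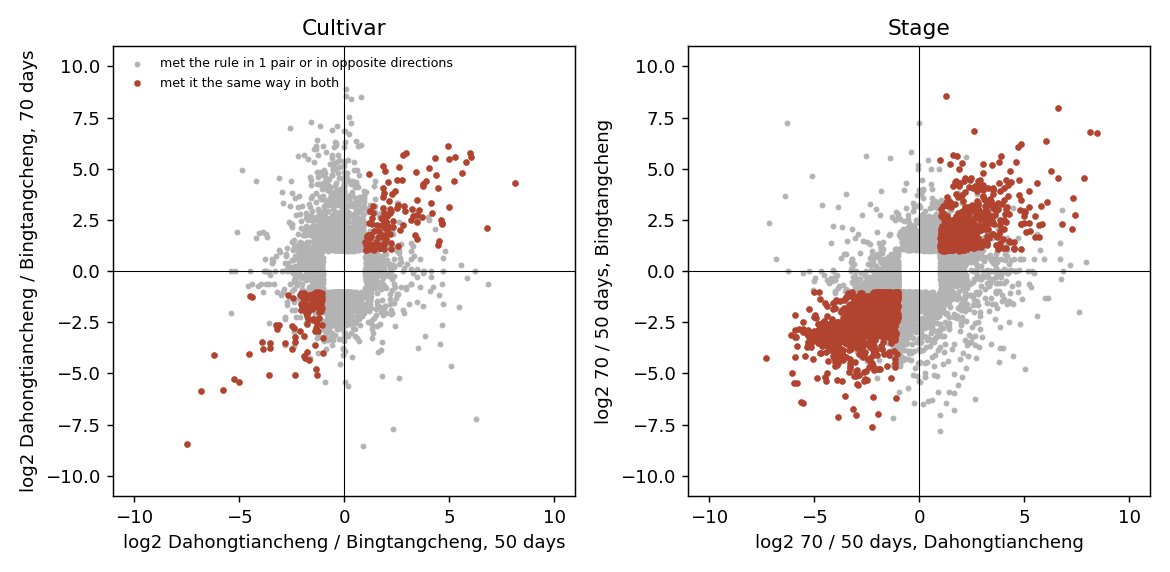
Log2 ratios of genes that met the size rule in at least 1 of the 2 pairs shown, between the cultivars at 50 days (horizontal) and 70 days (vertical) on the left, and between the stages in Dahongtiancheng (horizontal) and Bingtangcheng (vertical) on the right. Red points met the rule the same way in both pairs (219 genes on the left, 1843 on the right), and grey points did not.

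The third comparison asked whether the cultivars differed in how expression changed from 50 to 70 days. The ratio of Dahongtiancheng to Bingtangcheng was at least 2-fold larger at 70 than at 50 days for 1109 genes and at least 2-fold smaller for 942, counting genes whose 99% counting interval excluded no change. This interval was adopted after a first count by another rule had been seen, which gave 1518 and 1168 genes. With the medians of the level bins removed the numbers were 992 and 1064. That step takes out any shift that depends on level, so it cannot by itself settle the direction of the excess. The alternatives fixed before the data were examined all kept more increases than decreases. They ranged from 872 and 826 with a floor of 5 CPM to 434 and 220 with a fold threshold of 4. The log2 ratio between the cultivars had a standard deviation over genes of 0.64 at 50 days and 0.95 at 70 days. The ratio of ratios is the difference of these 2 log2 ratios, which were weakly correlated (r = 0.127). Its standard deviation is therefore larger by construction and says nothing of how the cultivars changed between the stages. With 1 library per combination, a cultivar difference in the change from 50 to 70 days cannot be told apart from variation between libraries. The largest increases of the ratio were in orange1.1t00607 (unplaced sequence, 6988034 to 6989803), with 1 fragment in Dahongtiancheng and 81 in Bingtangcheng at 50 days and 88 and 1 at 70 days, and in Cs1g14710 (chromosome 1, 18015823 to 18016274), with 0 and 10 fragments at 50 days and 373 and 1 at 70 days. The largest decreases were in Cs1g21100 (chromosome 1, 24050431 to 24052317), with 169 and 0 fragments at 50 days and 0 and 285 at 70 days, and in Cs7g25330 (chromosome 7, 25670607 to 25671884), with 181 and 31 fragments at 50 days and 0 and 398 at 70 days.

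A set of genes had a strongly reduced level in the 70-day Bingtangcheng library alone. By a rule chosen after the data were seen, 10 genes had at least 5 CPM in the other 3 libraries and a level in this one that was lower by a factor of 50 or more, with a count of 0 entered as 0. The corresponding number was 0 for the 50-day Dahongtiancheng library, 3 for the 50-day Bingtangcheng library and 5 for the 70-day Dahongtiancheng library. With a count of 0 entered as 3 fragments, the floor behind the folds given here, the numbers were 9 for this library and 0, 3 and 4 for the others in the same order. The 70-day Bingtangcheng library also had the fewest genes with at least 10 fragments, 15788, although its total was the largest. Genes with 0 fragments numbered 10099 in it, against between 9381 and 9551 in the others. The 10 genes had between 171 and 3443 fragments in Bingtangcheng at 50 days and between 0 and 27 at 70 days. They lay on 6 chromosomes and on unplaced sequence, and 2 of them overlapped other gene models, with which fragments could be shared. Cs8g19320 (chromosome 8, 21596984 to 21602088, minus strand) had levels of 281 and 221 CPM in Dahongtiancheng and Bingtangcheng at 50 days, and 560 and 1.54 at 70 days. Its level dropped 144-fold (95% counting interval 95.7 to 227) between the stages in Bingtangcheng, and at 70 days it was 364-fold (243 to 575) higher in Dahongtiancheng. Cs5g06570 (chromosome 5, 4065083 to 4066458, plus strand) had 189 and 150 CPM at 50 days and 292 and 1.80 at 70 days, an 83.1-fold (56.9 to 126) lower level at 70 days in Bingtangcheng. With 23 and 27 fragments in the 70-day Bingtangcheng library, Cs8g19320 and Cs5g06570 still reached the expression floor there. In Dahongtiancheng 9 of the 10 genes had a higher level at 70 than at 50 days, 3 of them by the size rule, and 1 was lower by the size rule. Between the cultivars at 50 days 1 of the 10 differed by the size rule.

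**Figure D3:**
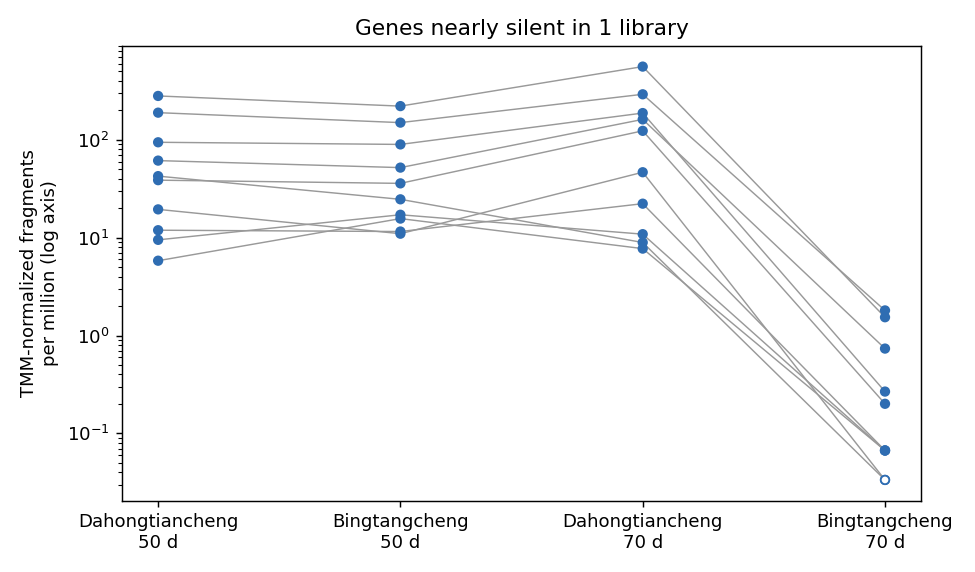
Level of the 10 genes strongly reduced in the 70-day Bingtangcheng library, selected with a count of 0 entered as 0 (vertical axis, TMM-normalized CPM on a log scale). Each line is 1 gene, and open points stand for a count of 0, drawn below the level of 1 fragment. Cs8g19320, the gene with the highest level in the other 3 libraries, had 221 CPM at 50 days and 1.54 CPM at 70 days in Bingtangcheng.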

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

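A difference of effect between groups was noted where genes met the size rule in opposite directions. Between the cultivars this held for 154 genes at 50 and 70 days, of which 53 were higher in Dahongtiancheng at 50 days and lower at 70 days and 101 the reverse. Between the stages it held for 130 genes, of which 95 were higher at 70 days in Dahongtiancheng and lower in Bingtangcheng and 35 the reverse. With 1 library per group the difference was not tested in either case.

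The test of the next pattern, the strongly reduced level of 10 genes in the 70-day Bingtangcheng library, was chosen after the result was seen. Assignment of the fragments to a gene within 15 kb stays open, because the median gain of such genes was 0.256 of the loss, between the bounds set for either answer. The gain was within 0.1 of the loss for 5 of the 10 genes, among them Cs8g19320 (-0.0399) and Cs5g06570 (0.0596), exceeded the whole loss for 3 (1.90 to 4.19), and was 0.584 and 0.452 for the 2 genes that overlap other models. A different response of the cultivars at this stage is a candidate explanation, as are a sequence variant, copies elsewhere in the genome, a difference between fruits or in dissection, and this library alone, none of which was tested.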

How the results depend on the processing

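Of 72 recomputed counts of genes, 59 stayed within 1.5 times the value given in the Results. An expression floor of 5 CPM left 482 genes between the cultivars at 50 days, 1194 at 70 days and 87 at both. A fold threshold of 4 left 316 and 713 genes between the cultivars at 50 and 70 days, 78 at both, 1491 and 1432 between the stages in Dahongtiancheng and Bingtangcheng, 679 in both, and 654 for the ratio of ratios. These follow from fewer genes passing a stricter rule. In the additive fit, the cultivar calls went from 0 to 23 without a filter and to 65 with DESeq2, and the stage calls from 1351 to 754 when tested against a fold of 1.5. The cause was not tested for the first 2. Scaling to total counts gave 3761, 3869 and 2066 genes between the stages in Dahongtiancheng, Bingtangcheng and both, of which 3200, 3005 and 1644 were among the 3597, 3420 and 1843, and it lowered the share of higher genes between the stages from 43.1% to 30.7% in Dahongtiancheng and from 37.6% to 22.5% in Bingtangcheng, and from 35.2% to 21.7% of those shared by both. Removing the median of each level bin, added after the data were seen, gave 1706 genes between the stages in both cultivars, of which 1543 were among the 1843. The deposited FPKM values gave 220 genes between the cultivars at both stages, of which 131 were among the 219. The 14 named genes kept their direction and met the rule in all 56 recomputed values (median-of-ratios, total counts, FPKM and prior count 0.5), but not their size. On the log2(FPKM + 1) scale, which understates changes of low genes, 12 of the 14 were smaller, such as 3.21 against 6.73 for Citrus_newGene_2305, -2.32 against -5.55 for Cs4g02820 and -6.13 against -13.51 for Cs1g21100. A prior count of 0.5 instead gave -7.52 for Cs4g02820 and -17.49 for Cs1g21100. Both rest on counts of 0, so their log2 sizes depend on the prior count and are not measured sizes. The first rule for the ratio of ratios, replaced after its count was seen, gave 2686 genes against 2051, with 1801 shared. The count of genes lost in the 70-day Bingtangcheng library was between 7 and 18 over 5 alternatives added after the data were seen, and exceeded those of the other 3 libraries in each. Genes on in 1 cultivar and off in the other fell from 27 to 14 or 11 under the 2 other thresholds. Alternatives for the gene lists were not run, since no list could be filled, and no library could be left out because each group has 1. Depth limits the weakly expressed genes most: 10 fragments, the floor used here, carry a wide counting interval.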

Other observations

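By rules chosen after the data were seen, genes that stood apart in a single library were counted for each library. By the on and off rule of at least 20 and at most 2 fragments, 42 genes were on in the 70-day Dahongtiancheng library alone, against 8 and 10 in the 50-day libraries of Dahongtiancheng and Bingtangcheng and 5 in the 70-day Bingtangcheng library. Genes off in a single library numbered 40 for Bingtangcheng and 24 for Dahongtiancheng at 70 days, and 14 and 6 at 50 days. These counts depend on the thresholds. With on at 50 fragments or off at 0, the 42 became 11 or 13 and the 40 became 13 or 14. With off at 0, genes off in the 70-day Dahongtiancheng library alone (4) were fewer than those off in the 50-day Bingtangcheng library alone (6). By the rule of at least 5 CPM and a factor of 50, with a count of 0 entered as 0, 8 genes were gained in the 70-day Dahongtiancheng library and 0 in the 70-day Bingtangcheng library, and 5 and 0 with a count of 0 entered as 3 fragments.

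Of the tests in this paragraph, those on overlap and on stage calls were chosen after the result was seen, and the one on level before. The pattern is the high share of cultivar differences among the Citrus_newGene models, 30 of 388 genes. Low expression of the new genes is argued against, as 0% of 10000 lists matched on level held as many. Counting of the same fragments in overlapping models is argued against for most of the 30, since 3.33% overlapped another gene that differed. The test counts overlap only, so it cannot decide on 1 transcript split into neighbouring models. Among expressed genes, some of the 30 lay beside a gene that differed the same way, such as Citrus_newGene_1269 beside Cs6g06760. The prediction for models assembled from single libraries, and so favouring differences of any kind, was that stage differences would also be frequent among them. Their raw share, 15.1% of 410 genes, was above the 11.6% of other genes, but 99.4% of lists matched on level held at least as many as their 62. This result cannot decide, because a stage difference had to be met in both cultivars. A model expressed in 1 library or 1 cultivar cannot meet it, so such assembly stays open. Presence or absence of sequence in 1 cultivar, or sequence that maps poorly to the reference, may account for the pattern and was not tested.

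All tests in this paragraph were chosen after the result was seen. Among genes on numbered chromosomes, 9 pairs of neighbouring expressed genes differed between the cultivars the same way at both stages, against 1.17 on average and at most 6 in 10000 shuffles of the calls along the genome. Stage calls also fell in neighbouring pairs beyond the shuffles, with 156 pairs against 104 on average and at most 140, so this is not particular to the cultivars. Citrus_newGene_549, Citrus_newGene_1081, Citrus_newGene_1269 and Citrus_newGene_1471 were members of cultivar pairs, and the other cultivar pairs held no such model. The pattern is therefore in part the same as the high share of cultivar differences among the Citrus_newGene models. A single transcript annotated as overlapping genes covers 11.1% of the 9 pairs (exact 95% upper bound 48.2%), which leaves 8. The test counts overlap only, so it cannot decide on 1 transcript split into neighbouring models that do not overlap. The median gap was 1064 bp in the 9 cultivar pairs and 7970.5 bp in the 156 stage pairs. Shared local regulation, or a structural difference between the cultivars, may be involved, and neither was tested.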
